A study of Mus musculus with 380 samples.

How the data were processed

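T cells were sorted from B16F10 tumours, a transplantable melanoma of C57BL/6 mice, grown in wild-type (WT) animals and in animals lacking Il27ra, the gene of the receptor chain specific for the cytokine IL-27. Per the labels' protocols, cells were lysed in plates, RNA was taken up on beads, cDNA was made and amplified with Smart-seq2, a full-length method without molecular identifiers, and libraries were made by tagmentation. The titles give each well a plate name, a genotype with an animal number, CD4 or CD8, and single cell or population. The protocol text names CD8+ cells for every well, which contradicts the titles of the CD4 plates. The titles were followed, and expression of Cd4 and Cd8a on each plate is reported with the results.

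The 380 samples came to 375 single-cell wells on 4 plates, 4 population wells (1 per plate), and 1 well left in no group because its title says WT and its genotype label says KO. Both genotypes carry a single animal label, so each group is 1 label and 1 plate; that a label stands for 1 animal was assumed. Genotype, animal and plate cannot be told apart, cells are not replicates, and no test between groups was possible. No p-value and no standard error between animals is given. Spreads over resampled cells cover variation between cells only, and tallies of genes beyond a size limit describe these plates only. Values are means over cells with the standard deviation (SD) between cells, shares of cells with exact Clopper-Pearson 95% intervals (for a count of 0, the limit given is 3 cells of the total, which bounds cells above the threshold and not cells expressing the gene), and, for gene lists, the percentile of the list median among 10000 random lists of equal size matched on mean expression (each member replaced by 1 of the 100 genes nearest on either side in mean level). These percentiles describe the plates and do not test the genotypes. Intervals cover counting error only.

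The values are FPKM, made by the authors with RSEM and normalized with TMM across wells, per the labels. The submitters' processing notes name Bowtie, RSEM and the mm10 build without versions. The annotation used by the authors is not given in the sources used here. The table holds 23420 genes, of which 6420 are at 0 in every well, and every column matched a sample title. FPKM keep no read counts. Where a fragment is counted whole, low values should step in multiples of the worth of 1 fragment. This was estimated per well from 8134 protein-coding genes with 1 annotated transcript. Of the low values, a median of 46.6% to 48.1% per plate came within 0.1 of a whole multiple, against 20% by chance, so whole reads were not recovered and no count test was run. The estimated worth of 1 fragment was 1.57, 1.37, 1.44 and 1.55 FPKM times kilobases (medians of the WT CD4, KO-labelled CD4, WT CD8 and KO-labelled CD8 plates), which served only as an approximate relative depth.

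A gene counted as detected in a cell above 1 FPKM. Wells with fewer than 1000 detected genes were left out. Expression was log2(FPKM + 1), so differences understate changes of low genes. A difference is the mean over cells of the KO-labelled plate minus that of the WT plate. The 27 gene lists, the filters, the comparisons and the rule for named genes were fixed before the data were examined. List members entered when detected in at least 5% of cells of either plate. 5 listed symbols did not occur in the table. For each comparison the named genes are the 12 highest and the 12 lowest (8 and 8 for CD8 minus CD4 in WT) by difference in mean log2, among genes detected in at least 20% of cells of either plate for which the difference in mean, the difference in share of cells and the difference between population wells have the same sign. Gene models without a proper symbol, T cell receptor and immunoglobulin segments and the genes of the list for the sex of the animal were left out of that ranking; other genes on the X chromosome were not. Il27ra, the co-inhibitory receptors, the genes the study worked with and the members of other lists with the largest absolute difference are named regardless. A cell counted as holding another cell type with 3 or more markers of a list for that type detected. Some of these lists, genes and alternatives are not reported here. No clustering was done and no doublet caller was run.

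Coordinates come from GENCODE release M21, which uses the same build. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data: 2 plates were drawn gene by gene from the WT CD4 plate with 200 genes altered, over 9051 genes. The direction was recovered for 48 of 50 genes raised by a factor of 4 and 48 of 50 lowered by the same factor, and for 50 of 50 at a factor of 16 either way. A list of 13 lowered genes lay at percentile 0, and 4.3% of 1000 lists of unaltered genes lay outside the central 95%. Since genes were drawn independently, that rate does not cover lists whose members vary together. Alternatives covered the pseudocount, the mean, filters on genes and wells, rescaling, adjustment for detected genes, a strict lineage filter, CD4 cells without Foxp3, the population wells, and, chosen after seeing the data, adjustment for the estimated fragment worth, an upper limit of 4000 detected genes, and a ranking without the population wells. The strict lineage filter kept cells with a Cd3 chain and a lineage gene of their plate detected (Cd4, or Cd8a or Cd8b1). Cells with a gene of the other lineage detected, or counted as holding another cell type, were dropped. The spread of a list median was taken from 1000 resamplings of the cells within each plate, which was also added after the data were seen.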

Results

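Tumour-infiltrating T cells were profiled one by one on 4 plates, CD4 and CD8 cells of 1 WT animal label and 1 Il27ra KO animal label, with 1 population well beside each plate. Of 93 WT CD4 wells, 92 had at least 1000 detected genes and were kept, as were 81 of 94 KO-labelled CD4 wells, 92 of 94 WT CD8 wells and 93 of 94 KO-labelled CD8 wells. The median number of detected genes per kept cell was 1907 on the WT CD4 plate, 1943 on the KO-labelled CD4 plate, 2214 on the WT CD8 plate and 2010 on the KO-labelled CD8 plate. The medians of the summed FPKM were 557772, 594889, 604093 and 580101 in the same order. The population wells held 10460 to 11225 detected genes. There were no replicates of any group, so every difference below is a description of these plates.

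The plates carried the T cell types their titles give. A Cd3 chain was detected in 89 of 92, 80 of 81, 91 of 92 and 93 of 93 cells. Cd4 was detected in 77 of 92 WT and 69 of 81 KO-labelled CD4 cells and in 0 CD8 cells of either plate, which allows a share above 1 FPKM of up to 3.26% of WT and 3.23% of KO-labelled CD8 cells. Cd8a was detected in 77 of 92 WT and 81 of 93 KO-labelled CD8 cells and in 6 and 4 cells of the WT and KO-labelled CD4 plates. Cd8b1 was detected in 81 of 92 WT and 86 of 93 KO-labelled CD8 cells, but also in 19.6% of WT and 27.2% of KO-labelled CD4 cells. Cells with 3 or more myeloid markers numbered 13 and 5 on the WT and KO-labelled CD4 plates and 9 and 0 on the CD8 plates. Those with 3 or more melanoma markers numbered 5, 2, 7 and 4 in the order of the plates above. One of the 8 melanoma markers, Tyr, was above 1 FPKM in 94.6% to 100% of cells of each plate, so in effect 2 others sufficed. Counts for B cell, NK cell, fibroblast or endothelial and erythroid markers were 4 or lower on every plate.

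The targeted gene did not separate the genotypes. Il27ra, at positions 84030294 to 84042589 of chromosome 8 (mm10), was detected in 46.7% of WT CD4 cells (95% interval 36.3 to 57.4) and 49.4% of KO-labelled CD4 cells (38.1 to 60.7). In CD8 cells the shares were 58.7% (47.9 to 68.9) and 61.3% (50.6 to 71.2). Mean log2 values were 2.88 ± 3.38 and 3.18 ± 3.43 (SD between cells) in CD4 and 3.73 ± 3.42 and 3.76 ± 3.34 in CD8. The population wells held 157.5 and 105.1 FPKM in CD4 and 98.2 and 68.5 FPKM in CD8. A value per gene cannot tell reads of a deleted part from reads of the rest of the gene, so these values do not check the labels. All directions between genotypes are therefore those of plates labelled KO against plates labelled WT.

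The study asked how IL-27 signalling relates to the co-inhibitory receptors of T cells in tumours, the surface proteins that restrain T cell activation. In CD8 cells most of them were lower on the plate labelled KO. Lag3 was detected in 34 of 92 WT cells (27.1% to 47.7%) and 13 of 93 KO-labelled cells (7.66% to 22.7%), with mean log2 values of 3.19 ± 4.30 and 1.07 ± 2.91. Pdcd1, the gene of PD-1, was detected in 41.3% (31.1 to 52.1) and 15.1% (8.48 to 23.97), at 3.40 ± 4.32 and 1.49 ± 3.52. Tigit was at 4.78 ± 4.28 and 3.21 ± 4.01, and Havcr2, the gene of TIM-3, at 2.04 ± 3.54 and 0.54 ± 1.47. Entpd1 (CD39) differed by -1.26, Ctla4 by -1.11 and Cd160 by -0.65. Cd244 (-0.47), Cd200r1 (-0.39), Cd200 (-0.30) and Klrg1 (0.24) lay between. Nt5e (CD73) was higher, in 26 of 93 KO-labelled against 11 of 92 WT cells, although its population wells differed by -0.34, and Btla differed by 0.51. Of the 13 receptors, 7 were lower by more than 0.5, 2 higher and 4 between. The list median was -0.65, at percentile 0.13 of matched random lists, whose central 95% ran from -0.51 to 0.01. The median gene detected in at least 20% of cells was itself shifted by -0.32 on this plate, and relative to it the list median was -0.33. After adjustment for the number of detected genes per well it was -0.32, and over the 7 receptors detected in at least 20% of cells it was -1.50. With the strict lineage filter (69 and 86 cells) the list median was -0.46, at percentile 1.06, against a lower limit of -0.41. The population wells gave a list median of -0.71, with Lag3 at 534 FPKM in WT and 65.9 FPKM in the KO-labelled well. That KO-labelled well also held melanoma transcripts, with Pmel at 3940 FPKM against 21.0 FPKM in the WT CD8 well. T cell lineage genes were lower in it too, with a median of -0.46 (0 higher and 5 lower by more than 0.5). Cd8a stood at 633.7 FPKM in the WT well and 314.6 FPKM in the KO-labelled well. The receptor median in these wells therefore cannot be read apart from a lower level of T cell genes. The share for Havcr2 depended on the detection threshold: 25.0% and 12.9% above 1 FPKM became 35.9% and 33.3% above 0 and 23.9% and 4.30% above 5.

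**Figure D1:**
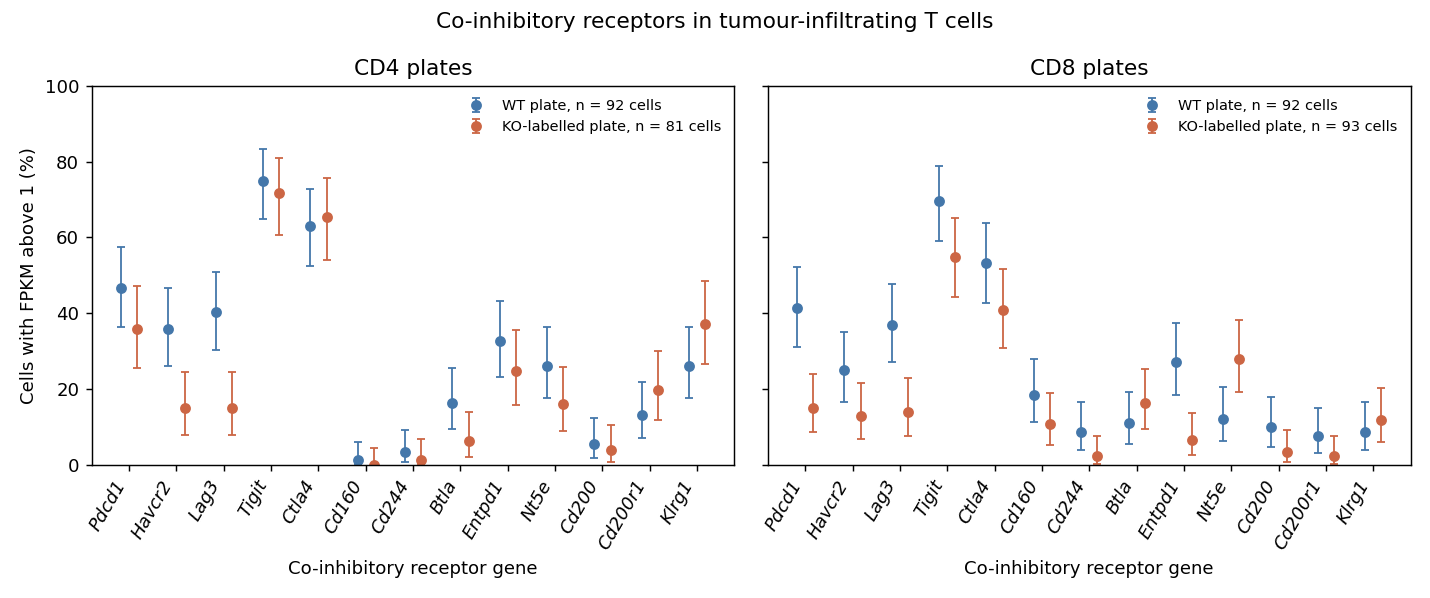
Share of cells (%, vertical axis) with each co-inhibitory receptor gene above 1 FPKM on the CD4 plates (left) and the CD8 plates (right), WT in blue and KO-labelled in orange, with exact 95% intervals that cover counting error only. Pdcd1 lies at 41.3% on the WT CD8 plate and at 15.1% on the KO-labelled CD8 plate.

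Beyond these receptors, the KO-labelled CD8 plate was lower in genes of effector T cells and higher in genes of naive and memory T cells. Among the 12 lowest genes by the fixed rule were the chemokine gene Ccl5 (10.04 ± 4.24 in WT, 6.30 ± 6.23 on the KO-labelled plate), Tnfrsf18, Anxa2, Serpina3g, Litaf, Tpi1, Rgs16, Ly6a, Nkg7 and Gbp6, with differences from -3.74 to -2.15. Among the 12 highest were S1pr1, the receptor that lets T cells leave tissues (3.24 ± 3.68 and 5.88 ± 3.49), Ccr7, Zfp868, Il7r, Tcp11l2, Emb, Tcf7, Lef1, Rnf7, Tsc22d3 and Pik3ip1, with differences from 2.64 to 1.85. Of 15 measured naive and memory genes 9 were higher by more than 0.5 and 2 lower, and their median of 0.90 lay at percentile 100 of matched lists. Ccr7 was detected in 52.7% of KO-labelled and 31.5% of WT cells. Of 24 cytotoxic and effector genes 15 were lower and 1 higher, with a median of -0.81 at percentile 0. Nkg7 differed by -2.15, the natural killer receptor gene Klrk1 by -1.98 and Gzmb, encoding granzyme B, by -1.97. The WT plate also held 9 cells with myeloid markers against 0 on the KO-labelled plate.

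Other lists also lay low on the KO-labelled CD8 plate. Exhaustion-associated transcription factors had a median of -0.94 (percentile 0.06) with 7 of 12 lower, among them Bhlhe40 (-2.06), Id2 (-2.04) and Nr4a2 (-1.96). Th1 genes had a median of -0.99 (percentile 0.21), with Cxcr6 (-1.77), Tbx21 (-1.33) and Ifng (-1.30). Genes listed for regulatory T cells had a median of -0.74 (percentile 0.02). Those with the largest differences, Capg (-1.63) and Tnfrsf1b (-1.46), are also expressed by activated T cells, and Foxp3 was detected in 2 of 92 WT and 1 of 93 KO-labelled cells. Cell cycle genes had a median of -0.54 (percentile 0.05) with 13 of 24 lower, such as Mcm5 (-1.30) and Cenpa (-1.29). After adjustment for the number of detected genes per well their median was -0.02, and without wells above 4000 detected genes, of which the WT plate had 7 and the KO-labelled plate 0, it was -0.18. Glycolysis genes had a median of -0.75 (percentile 0.34), with Pgam1 at -2.53 and Tpi1 at -2.47, but 0.35 in the population wells, where Gapdh was at 8542 FPKM in WT and 18210 FPKM in the KO-labelled well. Class I antigen presentation genes had a median of -0.68 (percentile 2.15), with Psmb10 at -1.82 and Tap2 at -1.63. Ribosomal protein genes were higher, with a median of 0.49 (percentile 99.57) and Rplp0 and Rps4x both at 0.87, but -0.21 in the population wells. The population values for glycolysis and ribosomal genes rest on the KO-labelled well that held melanoma transcripts. They cannot be read apart from those transcripts. STAT3 and IL-27 or IL-6 family targets lay high, with a median of 0.27 (percentile 99.40) but a mean of -0.11. Stat3 lay at -1.91 while 5 of 8 members lay within 0.5 of 0.

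Inside the central range of matched lists in CD8 were co-stimulatory receptors (median -0.05, with Tnfrsf18 at -3.15 and Tnfrsf9 at -2.12), mitochondrial respiratory chain genes (-0.60), immediate early and stress genes (-0.07), tissue residency and adhesion genes (-0.20), T cell lineage genes (0.01), the CD4 and CD8 lineage lists (-0.07 and 0.23), and markers of melanoma (-0.29), B cells (0.29), NK cells (-0.19) and fibroblasts or endothelium (0.41). Relative to the shift of the median gene, the immediate early list lay at 0.25, the residency list at 0.11 and the NK list at 0.13, on the other side of 0. The melanoma and CD4 lineage lists also crossed 0, to 0.02 and 0.25, and the co-stimulatory list to 0.27. Xist, the single measured gene of the sex list, differed by -1.44 in CD8 and 0.13 in CD4, both inside the range. Myeloid markers lay low, at -0.55 (percentile 0.03).

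**Figure D2:**
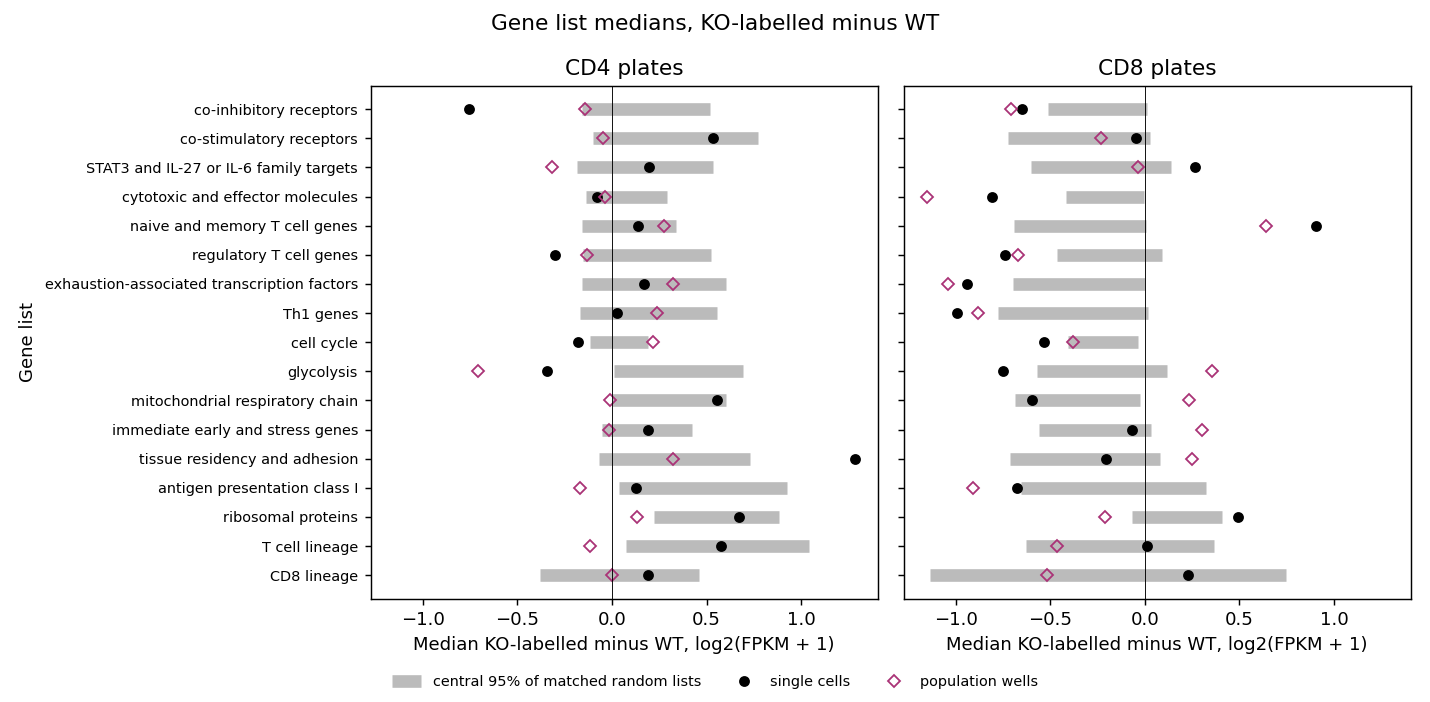
Median difference, KO-labelled minus WT, in log2(FPKM + 1) (horizontal axis) for gene lists with at least 3 measured members in both compartments (vertical axis), in CD4 (left) and CD8 (right). Black points are single cells, open diamonds the population wells and grey bars the central 95% of matched random lists. The co-inhibitory list lies left of its bar in single cells of both compartments, at -0.76 and -0.65.

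In CD4 cells the same receptor list was lower on the KO-labelled plate. Lag3 was detected in 40.2% of WT cells (30.1 to 50.96) and 14.8% of KO-labelled cells (7.90 to 24.4), at 3.52 ± 4.56 and 1.01 ± 2.71. Havcr2 was detected in 35.9% (26.1 to 46.5) and 14.8%, at 2.01 ± 3.21 and 0.89 ± 2.24. Entpd1 differed by -0.86, Tigit by -0.83, Nt5e by -0.81, Pdcd1 by -0.76 and Btla by -0.64. Ctla4 was level, at 6.06 ± 4.90 and 6.09 ± 4.86, as was Cd200 at -0.12. Klrg1 (1.12) and Cd200r1 (0.67) were higher. Cd160 and Cd244 were detected in at most 3 cells of either plate. The list median over 11 measured receptors was -0.76, at percentile 0 of matched lists (central 95% -0.16 to 0.52), with 7 lower and 2 higher. The median gene was shifted by 0.14, and relative to it the list lay at -0.90. In the population wells the list median was only -0.15, at percentile 20.3, and Pdcd1 and Btla were higher in the KO-labelled well by 0.12 and 0.39. That KO-labelled well was also higher in myeloid markers (median 2.18, 6 higher and 2 lower) and melanoma markers (1.04). Among CD4 cells without detected Foxp3 (51 and 50 cells) it was -0.20, at percentile 2.40. Entpd1 differed by 0.09 in those cells. With the strict lineage filter (49 and 46 cells) the list median was -0.42, at percentile 0.32, with 4 of 10 receptors lower and 2 higher. As a ratio of mean FPKM over cells the list median was -1.21.

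The genes that differed most in CD4 included some of tissue retention. The 12 highest on the KO-labelled plate were Cd69, an early activation and retention marker (4.10 ± 4.84 in WT, 7.08 ± 4.45 on the KO-labelled plate), Nfkbiz, Rgs2, Ms4a4b, H2afz, Rgs1, Ppp1ca, Btg2, Gata3, Emb, Rbl2 and Zfp868, with differences from 2.99 to 2.31. The 12 lowest were the protease inhibitor gene Serpina3g (4.10 ± 4.75 and 1.31 ± 3.20), Lag3, Gimap4, Irf1, Tnfrsf9, Eif4e, Anxa2, Saa4, Odc1, Igtp, Rac1 and Tgtp2, with differences from -2.79 to -1.59. Saa4 stood apart from the rest, being detected in 95.7% of WT and 77.8% of KO-labelled cells at low values and at 0.85 FPKM and 0 in the population wells, and on the CD8 plates it differed by 1.99. Tissue residency and adhesion genes had a median of 1.28 (percentile 99.99), with 10 of 12 higher and 0 lower, including Rgs2 (2.61), Rgs1 (2.47) and Itgb1 (1.95). Their population median was 0.32. Glycolysis genes had a median of -0.34 (percentile 0.03), with Tpi1 at -1.35, Aldoa at -1.26 and Gapdh at -0.77. It was -0.71 in the population wells.

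Genes listed for regulatory T cells had a CD4 median of -0.30 (percentile 0.29), with Il1rl1 at 1.36, Folr4 at -0.94 and Tnfrsf1b at -0.80, and 0.04 under the strict lineage filter. Foxp3 was detected in 44.6% of WT (34.2 to 55.3) and 38.3% of KO-labelled CD4 cells (27.7 to 49.7), a difference within the intervals. Cell cycle genes lay at -0.18 (percentile 0.38), with Cenpa at 0.69, Rrm2 at -0.63 and Mcm5 at -0.61, and at 0.22 in the population wells. Melanoma markers lay at -0.31 (percentile 1.36), with Tyr (0.41) and Tyrp1 (-0.40) furthest from 0 in opposite directions, and turned positive under 5 alternatives. Pecam1, the single measured gene of the fibroblast and endothelium list, differed by 0.93. Lists inside the central range of matched lists in CD4 were the co-stimulatory receptors (0.53, with Tnfrsf9 at -1.94 and Icos at 1.76), STAT3 and IL-27 or IL-6 family targets (0.19), cytotoxic and effector genes (-0.08, with Nkg7 at -2.23 and Ccl5 at -2.12), naive and memory genes (0.14, with Il7r at 1.46), exhaustion-associated factors (0.17), Th1 genes (0.02, with Cxcr3 at -1.94), respiratory chain genes (0.56), immediate early and stress genes (0.19, with Btg2 at 2.45 and Fos at 2.26), class I presentation (0.13), ribosomal proteins (0.67), the T cell, CD4 and CD8 lineage lists (0.58, 0.29 and 0.19) and myeloid markers (-0.14). Relative to the shift of the median gene, the naive and memory list lay at -0.01, the Th1 list at -0.12 and the class I list at -0.02. In the population wells Nkg7 (0.23), Ccl5 (0.18), Il7r (-0.18), Cxcr3 (0.049), Icos (-0.015) and Fos (-0.095) lay on the other side of 0, as did Nkg7 (0.67) and Il7r (-0.25) among cells without detected Foxp3. B cell, NK cell and erythroid markers had no measured member in CD4, and erythroid markers none in CD8.

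The genes the study itself worked with as parts or regulators of this receptor programme are not independent evidence of its direction, and few were measured. Il10, the gene of the inhibitory cytokine IL-10, was detected in 26.1% of WT (17.5 to 36.3) and 12.3% of KO-labelled CD4 cells (6.08 to 21.5), at 2.32 ± 4.10 and 0.84 ± 2.54. The transcription factor genes Maf (2.38 ± 2.89 and 2.12 ± 2.85) and Prdm1 (1.46 ± 2.46 and 1.83 ± 2.69) differed little between single CD4 cells, but by -0.80 and -1.16 between the CD4 population wells. Il10 differed by no more than 0.5 between those wells. Among CD4 cells without detected Foxp3, and under the strict lineage filter, all 3 genes, Il10 included, differed by no more than 0.5. The CD4 median over these 3 genes was -0.26, at percentile 16.7, with 0.30 under the strict lineage filter and -0.80, at percentile 3.60, in the population wells. In CD8 Prdm1 was the sole member above the detection minimum, in 20.7% of WT and 9.68% of KO-labelled cells, a difference of -0.57 at percentile 10.7, or -1.25 as a ratio of mean FPKM. Procr was detected in 0 of 92 WT CD4 cells, 0 of 81 KO-labelled CD4 cells and 0 of 93 KO-labelled CD8 cells, which allows shares above 1 FPKM of up to 3.26%, 3.70% and 3.23%, and in 2 of 92 WT CD8 cells. Pdpn was detected in 2 of 92 WT CD4 cells and in 0 cells of the other plates. Differences in Procr and Pdpn between single cells were not detectable at this depth. The CD4 population wells held Procr at 11.84 FPKM in WT and 0 in the KO-labelled well, and the CD8 population wells held Pdpn at 0 in WT and 7.67 FPKM in the KO-labelled well.

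Across 4894 genes detected in at least 20% of cells of any plate, the KO-labelled minus WT differences in CD4 and in CD8 correlated weakly, with Pearson r = 0.14 and Spearman rho = 0.09, and 47.2% of them had the same sign. The signs were taken without centring. The median gene was shifted by 0.14 in CD4 and -0.32 in CD8, opposite shifts that can lower the share with the same sign. Genes are not independent replicates. The 4 plates share no library, but the CD4 and CD8 plates of a genotype carry the same animal label, so both differences contrast the same labels. Without CD4 cells that had Foxp3 detected, r was 0.03. The single-cell differences correlated with those between population wells at r = 0.19 in CD4 and 0.22 in CD8, against 0.50 for CD8 minus CD4 in WT. Of the list medians, 8 of 24 in CD4 and 13 of 26 in CD8 lay outside the central 95% of matched lists. For lists of unrelated genes chance gives 1.2 and 1.3, but members of a fixed list can vary together and some lists share genes, so these counts are not a test.

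Levels of co-inhibitory receptors correlated across cells more than those of matched lists on every plate except the WT CD4 plate. The median pairwise Spearman rho across cells was 0.24 on the KO-labelled CD4 plate (10 receptors, percentile 100 of 1000 matched lists), 0.15 on the WT CD8 plate (13 receptors, percentile 99.6), 0.08 on the KO-labelled CD8 plate (10 receptors, percentile 99.3) and 0.11 on the WT CD4 plate (11 receptors, percentile 80.9). The highest pair on each plate was Tigit with Ctla4 (0.67), Havcr2 with Lag3 (0.70), Pdcd1 with Ctla4 (0.45) and Lag3 with Tigit (0.57), in the same order. All kept cells entered, those with Foxp3 detected included, and the correlation without them was not computed. The measured receptors also differed between plates.

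CD8 minus CD4 on the WT plates described the 2 compartments and checked the sort. The 8 genes highest in CD8 were Cd8b1 (0.74 ± 1.97 in CD4, 8.12 ± 3.53 in CD8), Ly6c2, Cd8a, Klrd1, Ms4a4b, Nkg7, Ccl5 and Ctsw, with differences from 7.38 to 4.35. The 8 lowest were Cd4 (6.52 ± 3.38 and 0.03 ± 0.14), Tnfrsf4, Folr4, Foxp3, Cd6, Capg, Tnfrsf9 and Itgb7, with differences from -6.50 to -2.64. Cytotoxic and effector genes were higher in CD8 (median 0.99, percentile 100, 18 of 24 above 0.5), and regulatory T cell genes (-1.06), co-stimulatory receptors (-1.12) and co-inhibitory receptors (-0.43) were lower, all at percentile 0. Among the co-inhibitory receptors Ctla4 differed by -1.98 and Tigit by -1.88, while Cd160 differed by 1.22. Maf was detected in 45.7% of WT CD4 and 2.17% of WT CD8 cells. The median gene was 0.37 higher in CD8. Tnfrsf9 turned to 0.89, Ctla4 to 1.12 and Tigit to 0.94 when CD4 cells with Foxp3 detected were left out.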

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

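The test for free melanoma RNA was chosen after the values had been seen, and so was the rule that led to Rgs2 (a difference of at least 1 in both compartments, in opposite directions, with the population wells on the same sides). Of the 11 genes that met it, Rgs2 had the largest gap in single cells, followed by S100a4 (1.70 in CD4, -1.83 in CD8, a gap of 3.53). All 11 were higher in CD4 and lower in CD8, the directions in which the median gene was shifted (0.14 in CD4, -0.32 in CD8). Rgs2, the gene of a regulator of G protein signalling, differed by 2.61 in CD4 and by -1.04 in CD8, plate labelled KO minus WT, a gap of 3.65 between the compartments. In the population wells it differed by only 0.20 in CD4 and -0.72 in CD8, less than S100a4 (1.01 and -1.47). Rgs2 was detected in 34.8% of WT and 65.4% of KO-labelled CD4 cells and in 43.5% and 31.2% of CD8 cells. Relative to the shift of the median gene, Rgs2 differed by 2.47 in CD4 and -0.72 in CD8 single cells. The CD8 value then falls short of the limit of 1. The difference between compartments was not tested, since each group is 1 plate.

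The population well of the KO-labelled CD8 plate held melanoma transcripts that the other 3 population wells held at far lower levels. Of the 8 fixed melanoma markers, 7 were at 10 or more times the highest of the other population wells, all but Tyr. Pmel stood at 3940 FPKM, Dct at 2448 FPKM and Gpnmb at 1906 FPKM, where the WT CD8 population well had 21.0, 35.7 and 2.18 FPKM. Of 8 further melanocyte lineage genes listed before the test, 6 reached the same bound, among them Slc24a5 at 617 FPKM and Slc45a2 at 561 FPKM. This is consistent with melanoma cells in that well. Free RNA shared by the whole plate was argued against, because the well lay above the mean of the single cells of its plate by a median of 5.92 on the log2 scale (3.03 to 7.34 over the 8 markers). No biological explanation was tested. Whether those transcripts alter the other values of that well was not tested.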

How the results depend on the processing

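Adjustment for fragment worth, the limit of 4000 detected genes and the ranking without population wells were chosen after seeing the data. The co-inhibitory median stayed negative under every alternative reported in both compartments, below its matched range in CD8 under all of them and in CD4 under all but the population wells. A list median counted as moved when it differed from the main one by more than 0.5 times the width of its matched range. By this rule the co-inhibitory median moved in CD4. It was -1.21 with the ratio of means, -0.42 with the strict lineage filter, -0.15 in the population wells and -0.20 without Foxp3. In CD8 it was -0.91 and -0.37 with pseudocounts of 0.1 and 10, -1.50 over members in at least 20% of cells, -0.99 with at least 2000 genes per well, -0.33 relative to all genes and -0.32 adjusted for detected genes. Prdm1 in CD8 was -1.25 with the ratio of means. The correlation was 0.0495 without a filter on low genes, 0.0555 with the strict lineage filter, 0.0921 in the population wells and 0.0252 without Foxp3. Direction was counted as turned only for lists outside their matched range and genes differing by at least 0.5. It turned in the population wells, in CD4, for cell cycle (0.22), melanoma markers (1.04), Pdcd1 (0.12), Btla (0.39), Nkg7 (0.23), Ccl5 (0.18), Il7r (-0.18), Icos (-0.015), Fos (-0.095), Folr4 (0.12), Cxcr3 (0.049) and Mcm5 (0.024), and in CD8 for STAT3 targets (-0.035), glycolysis (0.35), ribosomal proteins (-0.21), Nt5e (-0.34), Rps4x (-0.097), Rplp0 (-0.21), Pgam1 (0.87), Mcm5 (0.57) and Gapdh (1.09). It turned without Foxp3, in CD4, for melanoma markers (0.12), Entpd1 (0.091), Nkg7 (0.67), Il7r (-0.25), Folr4 (0.083) and Cenpa (-0.11), and in CD8 minus CD4 for Tnfrsf9 (0.89), Ctla4 (1.12), Tigit (0.94) and, by construction, Foxp3 (0.17). It turned with the strict lineage filter for regulatory T cell genes (0.041), melanoma markers (0.29) and Pecam1 (-0.10) in CD4. Melanoma markers in CD4 were 0.41 over members in at least 20% of cells and 0.012 adjusted for fragment worth. The turns in the CD8 population wells rest on the KO-labelled well that held melanoma transcripts and lower levels of T cell genes. They cannot be read apart from that content. Apart from Foxp3, the cause of the turns was not tested. Of 1822 values of named genes under alternatives, list members named in the report included, 1383 stayed within 1.5 times, or within 0.5 for small differences, 26 turned and the rest moved. Of 550 values of other lists 445 stayed within 0.5 times the width of their matched range, 10 turned and the rest moved. A further 42 values of genes with small differences and 65 of lists inside their range changed sign, 11 and 15 of them in the population wells. Ranked without the population wells, 9 of the 12 lowest and all of the 12 highest genes in CD4 were kept, 10 of the 12 lowest and 11 of the 12 highest in CD8, and all in CD8 minus CD4. The well with conflicting labels failed the filter of 1000 genes, so counting it as WT moved nothing. Filters on low genes do not apply to the named genes. The main correlation already uses the 20% filter, without which it was 0.0495, and centring cannot move it.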

Other observations

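The tests on reads from a part of Il27ra left in place and on a crossed technical batch, the resampling of cells, the fragment-worth alternative, the removal of genes near Il27ra and the tallies of genes by direction were chosen after results had been seen. By at least 1 in both compartments, with the population wells on the same sides, 17 genes were lower and 24 higher on both KO-labelled plates, and 11 differed in opposite directions. Without the condition on the population wells, 51 genes went the same way and 32 opposite ways. These tallies use differences without centring. They can depend on the opposite shifts of the median gene, 0.14 in CD4 and -0.32 in CD8. Serpina3g, encoding an intracellular protease inhibitor, was lower on both KO-labelled plates (-2.79 in CD4, -2.60 in CD8), as were Lag3 (-2.51 and -2.12), Tnfrsf9 (-1.94 and -2.12), Anxa2 (-1.77 and -2.79) and the interferon-induced GTPase gene Tgtp2 (-1.59 and -1.70). Zfp868 (2.31 and 2.37), Emb (2.35 and 2.16), Rnf7 (1.68 and 1.99) and Ier2 (1.63 and 1.79) were higher. These genes were picked after their values were seen, from those with the population wells on the same sides, by the smaller of the 2 differences.

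The co-inhibitory receptors were lower on the KO-labelled CD8 plate, and several sources other than IL-27 signalling stayed open. A technical batch that joins WT CD4 with KO-labelled CD8 would run the opposite way in CD4, where the median was -0.76, below its range by 0.60 with a spread of 0.30 over resampled cells. Without Foxp3-detected cells it was -0.20, below by only 0.0041 with a spread of 0.28, and in the population wells -0.15, inside the range, so another cause may lower it in CD4 and the batch stays open. Adjusted for detected genes or for fragment worth, the CD8 median lay at percentiles 0.29 and 1.17, but below its range by only 0.10 and 0.03, less than spreads of 0.18 and 0.22. Without adjustment it also lay close to its range, at -0.65 against a lower limit of -0.51, and that spread was not resampled. Margin and spread therefore cannot show whether either adjustment accounts for the difference. Gene number and depth therefore stay open, although adjustment for fragment worth moved the median only from -0.65 to -0.59, and so does a different mix of naive and effector cells; with 1 animal label per genotype, plate, animal and genotype cannot be told apart.

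Il27ra was detected in up to 61.3% of cells on the KO-labelled plates. Reads from a part of the gene left in place may explain this, but 1 value per gene cannot show which exons the reads came from. Exchanged labels in 1 compartment were tested through the genes within 20 Mb of Il27ra, where a strain segment around the knockout would differ the same way in CD4 and CD8. Over such genes the 2 differences correlated at 0.40, percentile 98.5 of 2475 runs of neighbouring genes. Without Zfp868, 14.4 Mb away, the percentile was 89.01, and without Ier2 as well, also inside the window, it was 78.7. Zfp868 was the gene whose removal lowered the correlation most, and the runs were not trimmed the same way. A fall in percentile was thus built in, so the removals cannot decide the question. The result depends on these genes, and exchanged labels stay open. No biological explanation was tested.

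Of 461 genes detected in at least 60% of cells on every plate, 3 (Saa4, Gm4841 and Lonrf1) had medians at least 2 times higher on the WT CD4 and KO-labelled CD8 plates than on the other plates. All 3 were below 20 FPKM in every population well. The other pairings of the plates gave 1 to 6 genes, with 0 of them that low. In all, 57 genes were detected in at least 60% of cells on every plate while below 20 FPKM in every population well. The cause was not tested. The well in no group held 649 detected genes and a summed FPKM of 51038.7, of which Rn45s made 41.1%, with Cd4 and Il27ra at 0.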
